A study of Mus musculus with 16 samples.

How the data were processed

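The series compares expression arrays of 3 groups: melanocytes with no disease (4 arrays), melanomas of the iMet mouse model (6) and melanomas of the iHRAS* mouse model (6). Per the labels' protocols, RNA was extracted with Trizol followed by RNeasy columns, reverse transcribed with an oligo-dT primer carrying a T7 promoter and transcribed in vitro into biotinylated cRNA, which was hybridised to Affymetrix mouse 430A 2.0 arrays. Each sample was placed in its group by its title. The tumour titles of the iHRAS* group use the name iRas, and their genotype labels give the same construct as the design text.

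The authors deposited 1 table of values for all 16 arrays, 22690 probe sets each. The values ran from −4.07 to 14.53, which is the range of log2 signal, and were taken as log2 expression as deposited. How probe signals were summarised and normalized is not given in the sources used here. Medians of the deposited columns ran from 6.56 to 7.28. Before the data were examined, it had been fixed that the values would be quantile-normalized if these medians spread by more than 0.3, and they spread by 0.719. The main values are therefore quantile-normalized log2 values, and the deposited scaling and centring of each array on its median were alternatives. Quantile normalization removes any true difference between arrays in the distribution of signal as a whole, so that higher and lower calls are relative to the rest of the array. Control probe sets (64) were left out, and 22626 entered the normalization.

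Probe sets were named through the platform annotation that came with the series: 20380 had 1 gene symbol, 691 had several and 1555 had none here. Of the first kind, 20351 matched the reference gene table by gene ID and 0 symbols changed. Probe sets with several symbols or none were not used for genes. A gene was represented by its probe set with the highest mean, which gave 12393 genes, 4956 of them with more than 1 probe set. Among called genes with 2 or more probe sets, another probe set was called in the opposite direction for 0 of 626 genes between the tumour models, 7 of 1160 for iMet tumours against melanocytes and 20 of 1265 for iHRAS* tumours against melanocytes. A gene was tested if its signal exceeded the 40th percentile (log2 6.21) on as many arrays as the smallest group holds, which left 8058 genes between the tumours and 8651 against melanocytes. Signals below that level lie near background, where a difference is poorly measured.

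Differences were fitted with limma (lmFit and eBayes, two-sided) on the log2 scale, with genes called at a Benjamini-Hochberg adjusted p under 0.05. The 12 tumour arrays were fitted alone for the comparison of the models, and all 16 arrays together for the comparisons with melanocytes. Differences are iMet minus iHRAS*, or tumour minus melanocyte, with their standard errors. Every adjusted p of a gene in the text comes from these limma fits, and that of a list from limma's camera over the lists of a comparison. Single values, such as the engineered genes and array measures, were compared with two-sided exact permutation tests, whose smallest possible p for 6 against 6 arrays is 0.002165. The 37 measures per array formed one family for adjustment.

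The text names genes by a rule fixed before the data were examined: the 12 largest increases and 12 largest decreases between the models among called genes whose group ranges do not overlap, the 8 largest of each kind against melanocytes, the engineered genes, and up to 4 members of each list with the smallest p, with members that went against their list. Genes named outside this rule, such as the last members of a list with few calls, were chosen after their values were seen. The 25 gene lists, of pathways and of cell types that a skin melanoma could hold, were fixed at the same time and hold 380 genes, of which 344 had a probe set; Fscn1 is the only gene on more than 1 list. The invasion candidates were written from what is known of the study and are not given by the labels. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. At the preset correlation, random splits of the arrays passed a median of 6 or 7 lists, so a pass there is weak evidence alone. Of the lists, lymphocyte markers and red blood cell markers had fewer than 2 members tested in at least 1 comparison and were then not tested as lists.

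Because both comparisons against melanocytes use the same arrays, their resemblance was set against 100 simulated runs of unchanged groups, against the expectation for independent lists and against values with the melanocyte arrays divided between the models. Each count was also compared with 100 random splits of the same arrays. The fits were tested on simulated data with known changes added to a random set of genes. Between the tumour models 61.7% of genes changed by log2 1 were recovered and 89.9% of those changed by log2 2 (7973 and 7988 genes run). For iMet tumours against melanocytes the shares were 63.6% and 89.3% (8631 and 8606 genes), and for iHRAS* tumours against melanocytes 62.1% and 86.2% (8607 genes each). No changed gene was called in the wrong direction, and 2.76% to 7.35% of calls were false.

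Alternatives fixed before the data were examined were the other scalings, no dim filter or the 60th percentile, all probe sets or their mean, leaving out probe sets with suffixes of shared or ambiguous targets, a trended robust variance, array weights, other arrays in the fit, the replicate number as a block, stricter thresholds and leaving out each array in turn. Settings without pairs of doubted arrays, and one with keratinocyte and endothelial marker means as covariates, were added after seeing the data. In that last setting the 2 marker lists and their members, which define the covariates, were left out of the results for lists and named genes, but all 8058 genes entered the count. Pseudocounts had been planned for linear values only and were not run. No arrays were left out of the main values, and no pair of arrays held identical values. R 4.3.3 with limma 3.58.1 was used, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for figures.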

Results

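Messenger RNA levels were measured on Affymetrix mouse 430A 2.0 arrays in 16 samples. Melanocytes with no disease gave 4 of the samples. Cutaneous melanomas of the iMet mouse gave 6 more. In that model a tetracycline-inducible Met transgene, which encodes the receptor of hepatocyte growth factor, is switched on in melanocytes through a tyrosinase promoter on a background lacking Ink4a and Arf. Melanomas of the iHRAS* mouse, which is built in the same way with an activated form of HRAS, gave the last 6. The labels of the tumour samples speak of isolated melanoma cells, whereas the series' design text speaks of RNA from melanomas, and the sources used here do not settle which was hybridised. The labels do not say that the samples of a group came from separate animals, so the p-values below measure the spread between these samples. The number of arrays limited the precision.

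The array profiles separated by group. The first principal component held 41.8% of the variance and placed the melanocytes at 72.5 to 91.9 and every tumour below 0. On the second component, with 17.8%, the iMet tumours lay at −53.1 to −23.3 and the iHRAS* tumours at 24.5 to 45.7. The median correlation between arrays, taken across genes, was 0.915 among iMet tumours, 0.859 among iHRAS* tumours and 0.899 among melanocytes. The melanocyte arrays fell into 2 pairs, 1 with 3 (0.958) and 2 with 4 (0.940), with 0.867 to 0.915 across the pairs. Keratinocyte marker means were 7.69 and 6.79 in arrays 1 and 3 and 9.19 and 9.04 in arrays 2 and 4. Fibroblast means were 10.44 and 10.98 against 8.89 and 8.28. Settings without a pair were chosen after the data were seen. Between the tumour models the median correlation was 0.815, and between melanocytes and tumours 0.714 for iMet and 0.708 for iHRAS*. Xist, transcribed from the inactive X chromosome of females, was at log2 6.60 and 6.33 in iHRAS* tumours 5 and 6, in which the Y-linked Eif2s3y reached 6.40 and 7.20. The other 14 arrays had Xist at 10.9 to 13.1. The spike-in control bioB, added in equal amounts by design, was at log2 7.92 ± 0.29 (SD, n = 6) on the iHRAS* arrays. It was higher on every iMet array, at 8.90 ± 0.17 (SD, n = 6, exact permutation p = 0.002165, adjusted p = 0.0080). It was 8.91 ± 0.16 (SD, n = 4) on the melanocyte arrays. The bioC control was also higher on the iMet than on the iHRAS* arrays, by 0.63 (exact permutation p = 0.002165; adjusted p = 0.0080), and the brighter bioD control did not separate the tumour groups (exact permutation p = 0.699).

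**Figure D1:**
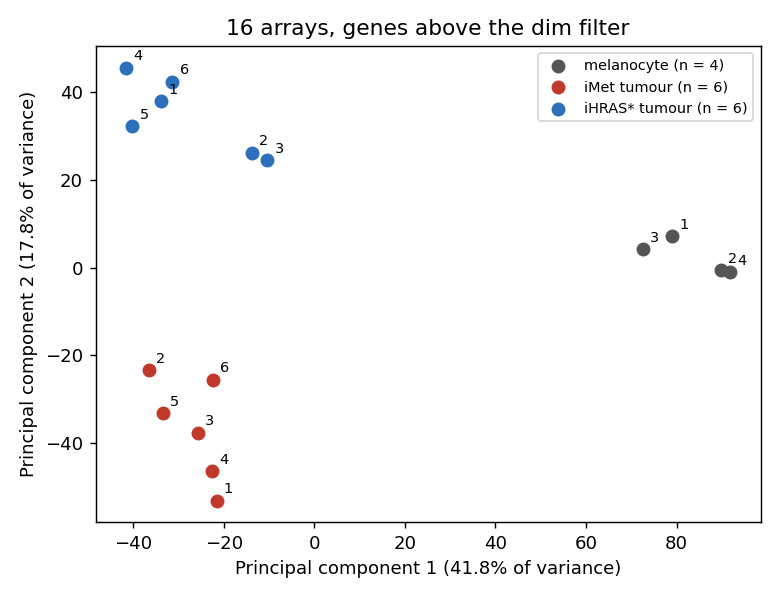
Each point is an array, placed by its scores on the first (41.8% of variance, x axis) and second (17.8%, y axis) principal components of the quantile-normalized log2 values and coloured by group. Melanocytes lie at 72.5 to 91.9 on the x axis.

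The engineered genes were examined first. Met had a mean log2 signal of 9.47 ± 0.55 (SD, n = 6) in iMet tumours, 8.29 ± 0.89 (SD, n = 4) in melanocytes and 6.94 ± 0.77 (SD, n = 6) in iHRAS* tumours. It was higher in every iMet tumour than in any iHRAS* tumour, by 2.53 ± 0.35 log2 (SE), or 5.78-fold (limma adjusted p = 0.00062). Against melanocytes it rose by 1.18 ± 0.44 in iMet tumours (adjusted p = 0.0479; exact permutation p = 0.0333) and fell by 1.35 ± 0.44 in iHRAS* tumours (adjusted p = 0.0244; exact permutation p = 0.0190). Neither call against melanocytes was secure. The increase in iMet tumours was 0.84 without melanocyte array 3 (adjusted p = 0.164) and 1.04 without melanocyte array 1 (adjusted p = 0.127), and it also missed the threshold without iMet array 1, 3, 4, 5 or 6, at 1.08 to 1.18 (adjusted p = 0.0695 to 0.0872). The decrease in iHRAS* tumours was −1.14 without melanocyte array 2 (adjusted p = 0.0853) and −1.07 without melanocyte array 4 (adjusted p = 0.0880). Whether the probe set also detects the transgene is not given in the sources used here. Hgf, the ligand of the receptor, had a mean of 7.96 in iMet tumours, 5.03 in iHRAS* tumours and 5.07 in melanocytes, and rose in iMet tumours over melanocytes by 2.89 ± 0.41. It was not tested between the models because iMet array 6, at 6.17, missed the 6.21 cut-off, but no iHRAS* array exceeded 5.74. No probe set was named Hras here, so the HRAS transgene was not analysed here. Cdkn2a, the locus of Ink4a and Arf, lay far below the 40th percentile of signal (log2 6.21) in all groups, at 3.34 ± 1.29 (SD, n = 6) in iMet tumours, 4.05 ± 0.52 (SD, n = 6) in iHRAS* tumours and 4.37 ± 0.55 (SD, n = 4) in melanocytes. It was therefore not tested across the array, and exact permutation tests of the 3 pairs of groups gave p = 0.258, 0.171 and 0.376. Whether the probe set lies in the deleted part is unknown, so it does not check the genotype.

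The comparison of the models asked which transcripts separate tumours of a lineage able to metastasise from tumours of one that is not, as the series' design text frames it. The largest differences were of genes lower in iMet than in iHRAS* tumours. Nrcam, a neuronal cell adhesion molecule, was at log2 3.0 in iMet and 10.5 in iHRAS* tumours, a difference of −7.47 ± 0.55 (SE; adjusted p = 1.3e-05). The transcription factors Sox2 and Foxd3, which act in neural stem cells and in early neural crest, differed by −7.39 ± 1.10 and −6.35 ± 0.25. The neuregulin receptor Erbb3 differed by −4.66 ± 0.34. The neurofilament genes Nefl and Nefm were at −5.66 ± 0.55 and −5.03 ± 0.95, the collagenase Mmp1a at −5.77 ± 0.43, the retinoic acid synthesising enzyme Aldh1a3 at −5.57 ± 0.68 and the imprinted gene Phlda2 at −4.86 ± 0.55. Also among the 12 largest decreases were Slc14a1 (−5.20 ± 1.07), a urea transporter, Fbn2 (−5.01 ± 0.86), a fibrillin of elastic fibres, and the kallikrein Klk6 (−4.93 ± 0.95).

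Among the genes higher in iMet tumours, Ogn, a small proteoglycan of the extracellular matrix, showed the largest increase, at 4.79 ± 0.59 or 27.6-fold, from log2 6.18 to 10.97 (adjusted p = 0.000295). The angiopoietin-like factor Angptl7 rose by 3.83 ± 0.63, the homeobox gene Hoxb2 by 3.67 ± 0.76, the acid phosphatase gene Acpp by 3.46 ± 0.30 and Zfpm2, a cofactor of GATA transcription factors, by 3.46 ± 0.45. The peptidase gene Mme, also known as CD10, rose by 3.07 ± 0.43, the caveolar gene Cavin2 by 3.11 ± 0.49 and the matrix gene Efemp1 by 3.10 ± 0.65. Increases of 3.20 ± 0.52, 2.88 ± 0.27 and 2.83 ± 0.31 were measured for Tmem100, for the leukotriene synthase Ltc4s and for Rgcc. The chemokine gene Ccl12 rose by 3.08 ± 0.98, but its adjusted p passed 0.05 when any 1 of the iMet arrays or iHRAS* array 3 or 4 was left out, with values of 2.89 to 3.25. Signals well under the 40th percentile lie near background, so the size of a difference against such a level, as for Nrcam, Sox2 and Foxd3 in iMet tumours, is uncertain even where its direction is clear.

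**Figure D2:**
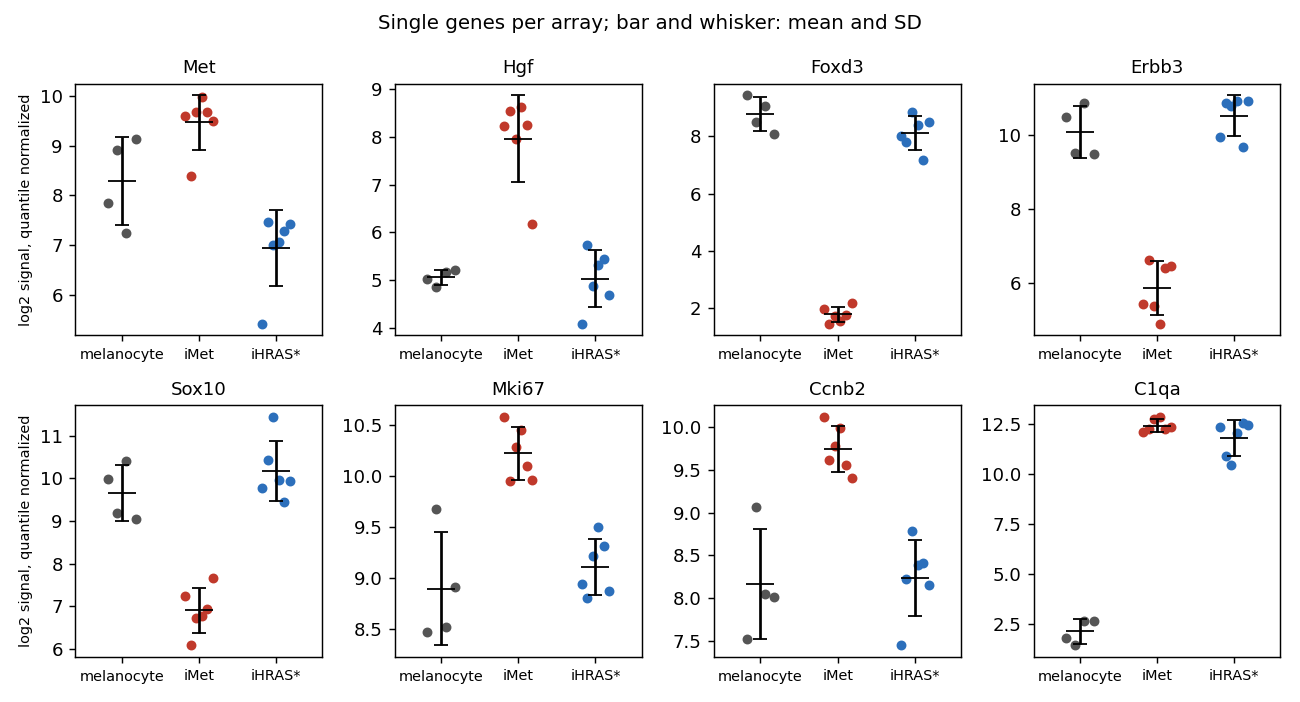
Quantile-normalized log2 signal (y axis) of Met, Hgf, Foxd3, Erbb3, Sox10, Mki67, Ccnb2 and C1qa on each array (points) in melanocytes, iMet tumours and iHRAS* tumours; bars mark the group mean ± SD. Met averages 9.47 in iMet tumours.

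Of the 7 Schwann cell and neural crest markers tested between the models, 5 fell in iMet tumours and none rose, 6 when adjusted over the list alone, and the list median was −2.76. Besides Foxd3, Erbb3 and Sox2, these were Egr2, a regulator of myelination, at −2.23 ± 0.47, and the neurotrophin receptor Ngfr at −2.76. The list ranked below other genes in limma's camera test (adjusted p = 1.33e-06; adjusted p = 0.025 with an estimated correlation). Of 7 pigmentation and melanocyte lineage genes, 3 fell, also 3 when adjusted over the list alone. They were Sox10, the transcription factor that maintains the lineage, at −3.26 ± 0.33, its partner Pax3 at −2.33 ± 0.44 and the melanosome gene Pmel at −1.15 ± 0.31. This list (median −0.42) passed camera (adjusted p = 0.0254). It was lost with an estimated correlation (adjusted p = 0.261), without iHRAS* array 4 (0.053, median −0.25) and with no dim filter (0.160). The same held without iHRAS* arrays 5 and 6 (0.0659) and with the keratinocyte and endothelial means as covariates (0.0816). The keratinocyte marker mean was lower in iMet tumours too, by 2.62 log2.

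Genes of cell division were higher in iMet tumours. Of the 22 tested, 19 rose and none fell, 20 when adjusted over the list alone, with a median of 1.03. Cyclins Ccna2 and Ccnb2, which drive entry into mitosis, rose by 1.61 ± 0.19 and 1.51 ± 0.20, the replication licensing factor Mcm4 by 1.03 ± 0.13 and the polymerase clamp Pcna by 0.92 ± 0.13. The list passed camera at adjusted p = 2.71e-12 (adjusted p = 0.135 with an estimated correlation), and its mean was 9.72 ± 0.23 (SD, n = 6) in iMet tumours against 8.71 ± 0.28 (SD, n = 6) in iHRAS* tumours, higher in every iMet tumour (exact permutation p = 0.002165; adjusted p = 0.0080). Targets of the tumour suppressor p53 went the other way. Of 11 tested, 7 fell and none rose, 9 when adjusted over the list alone, with a median of −0.81. The apoptosis gene Pmaip1 was at −2.74 ± 0.33, the cyclin-dependent kinase inhibitor Cdkn1a at −1.72 ± 0.25, Phlda3 at −1.25 ± 0.17 and Ccng1 at −0.88 ± 0.11. The p53 list passed camera at adjusted p = 4.79e-06 (adjusted p = 0.025 with an estimated correlation). Markers of other cells moved alongside both lists: the keratinocyte mean was lower by 2.62 and the endothelial mean higher by 0.83 in iMet tumours.

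Marker genes of several other cell types differed between the models. Of 12 endothelial markers, 9 rose in iMet tumours, and when adjusted over the list alone 10 rose and 1 fell; the median was 1.19. The junction genes Esam and Pecam1 rose by 1.40 ± 0.31 and 1.33 ± 0.30, the endothelial mucin Emcn by 1.46 ± 0.32 and Egfl7 by 1.07 ± 0.25 (camera adjusted p = 0.00244; adjusted p = 0.523 with an estimated correlation). The number that rose was 5 without iMet array 1, 2 or 5 or iHRAS* array 3 or 4, and 2 members fell without iMet array 2 and 1 without iHRAS* array 2. Of 13 keratinocyte markers, 4 fell, 5 when adjusted over the list alone, with a median of −2.78. The epithelial adhesion genes Cdh1 and Epcam were at −2.86 ± 0.54 and −3.66 ± 0.79 and Perp at −2.83 ± 0.73, whereas the desmosome gene Dsp, at −3.67 ± 1.08, lost its call without iMet array 1, 4 or 5 or iHRAS* array 2, 4 or 6, at −3.61 to −2.94. The keratinocyte list passed camera at adjusted p = 0.000126 (adjusted p = 0.429 with an estimated correlation). Its mean varied far more among iMet tumours, at 7.05 ± 2.04 (SD, n = 6), than among iHRAS* tumours, at 9.68 ± 0.84 (SD, n = 6).

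Of 14 macrophage markers, 2 rose in iMet tumours and 1 when adjusted over the list alone. They were the integrin Itgam at 1.47 ± 0.34 and the mannose receptor Mrc1 at 1.01 ± 0.32, the latter losing its call without any 1 of iMet arrays 1, 2, 3 and 5 or iHRAS* arrays 1, 2, 3 and 4, at 0.89 to 1.04. The macrophage list (median 0.76; camera adjusted p = 0.0158, adjusted p = 0.672 with an estimated correlation) missed the threshold without iHRAS* array 2 (adjusted p = 0.059) or 3 (adjusted p = 0.127, median 0.47). It also missed it without iHRAS* arrays 2 and 3 (adjusted p = 0.669) or 3 and 4 (0.0624), as deposited (0.130) and in limma's fry test (0.138), which asks only whether a list's own genes move one way. Antigen presentation genes had a median of −0.56 and passed camera (adjusted p = 0.0265; adjusted p = 0.687 with an estimated correlation), yet none of the 13 passed on its own, in all genes or adjusted over the list alone. That list missed the threshold without iMet array 1 or 6 or iHRAS* array 1, 4 or 5, at adjusted p = 0.061 to 0.108, without iHRAS* arrays 5 and 6 (0.122), with the covariates (0.0816) and in fry (0.269). Its median was −0.86 and −0.88 without iHRAS* array 2 or 3.

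**Figure D3:**
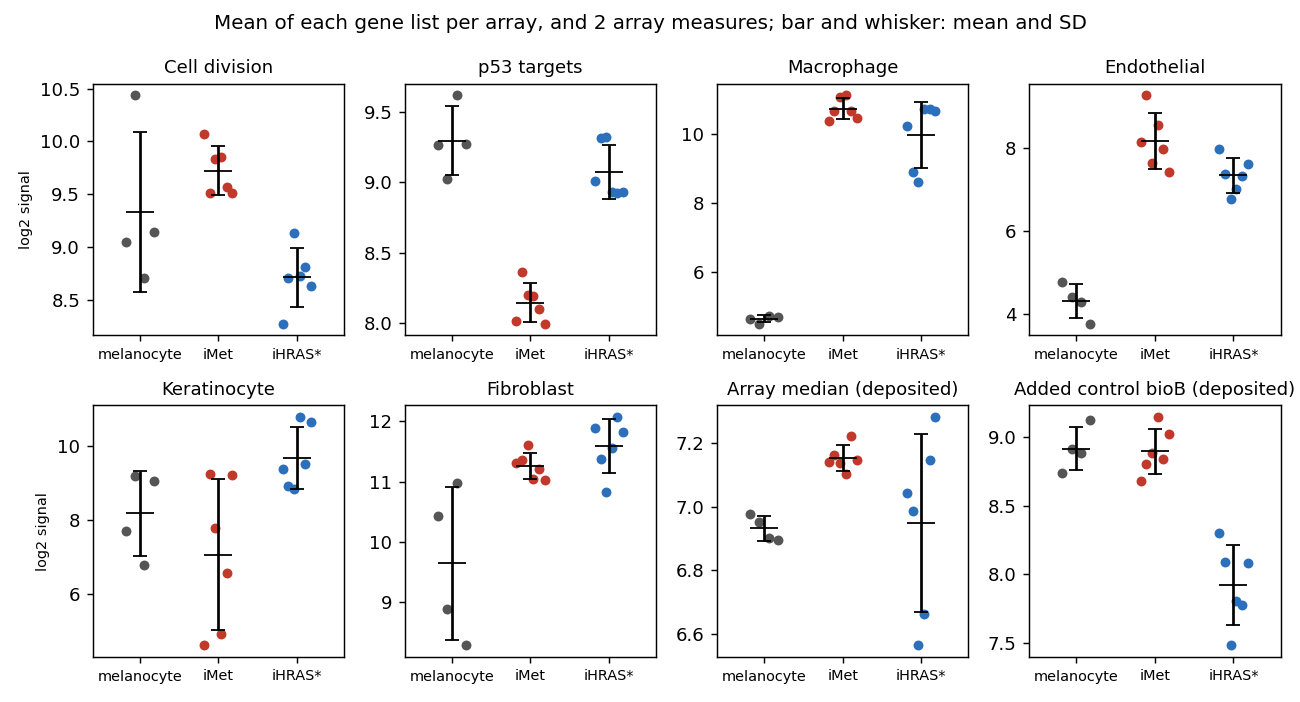
Mean log2 signal (y axis) of the cell division, p53 target, macrophage, endothelial, keratinocyte and fibroblast lists on each array (points) by group, with the median of all probe sets and the bioB spike-in as deposited; bars mark the mean ± SD. The macrophage mean is 4.63 in melanocytes.

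Genes of adhesion and invasion changed in both directions. Of 16 integrins and adhesion receptors, 5 fell in iMet tumours and none rose, also 5 when adjusted over the list alone (median −0.71; camera adjusted p = 0.000448, adjusted p = 0.0482 with an estimated correlation). The neural adhesion molecule L1cam was at −3.13 ± 0.27, the hyaluronan receptor Cd44 at −0.73 ± 0.12 and the laminin receptor Itga6 at −0.91 ± 0.15, followed by Itga5 and Itgb3. Itgb3 stood at −2.67 ± 0.75 and lost its call without iMet array 3 or 5, at −2.47 and −2.41, and the number that fell was then 3. The list of 6 invasion candidates was written from what is known of the study, which is understood to have chosen them with these samples, so it is not independent evidence. Of its 4 tested members, 3 rose, also 3 when adjusted over the list alone (median 1.5; camera adjusted p = 0.0126, adjusted p = 0.0858 with an estimated correlation). They were the kinetochore gene Ndc80 at 1.77 ± 0.25, the actin bundling gene Fscn1 at 0.53 ± 0.14 and the macrophage receptor gene Vsig4 at 1.74 ± 0.52. Vsig4 lost its call without any 1 of iMet arrays 1, 2, 3 and 6 or iHRAS* arrays 1 to 5, at 1.38 to 1.76. The phosphatase gene Acp5 had a difference of 1.27 ± 0.61 that did not pass. The lower keratinocyte and higher endothelial means of iMet tumours moved alongside both lists, and with these means as covariates Cd44 (−0.62, adjusted p = 0.130), Itga6 (−0.81, 0.0919), Ndc80 (1.69, 0.0612) and Fscn1 (0.53, 0.217) lost their calls.

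Of 17 matrix proteases and inhibitors, 2 rose and 3 fell (camera adjusted p = 0.5). The inhibitor Timp1 was at −1.89 ± 0.16, the plasminogen activator Plat at −1.22 ± 0.20 and the urokinase receptor Plaur at −0.85 ± 0.19, while the metalloprotease Adam12 rose by 1.91 ± 0.35, as did Timp2. Only 1 rose without iMet array 2 or 4 or iHRAS* array 4. Of 13 mesenchymal transition genes, Twist1 rose by 0.74 ± 0.19 and N-cadherin, Cdh2, fell by 1.63 ± 0.24, with a list median of 0.08 and a mean of −0.00 (camera adjusted p = 0.994). Without iHRAS* array 4, 2 fell. Of 19 actin and motility genes, 2 rose, Wasf1 by 0.94 ± 0.22 and Fscn1, and 3 fell, among them the exchange factor Tiam1 at −1.18 ± 0.31 and Cttn at −0.54 ± 0.13 (camera adjusted p = 0.994). Without iHRAS* array 5, 5 rose. Cttn was at 0.06 when all of its probe sets were averaged. Adjusted over the list alone, 3 proteases or inhibitors rose and 3 fell, 1 mesenchymal gene rose and 1 fell, and 4 actin genes rose and 4 fell.

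Of 13 genes around the MET receptor, Met rose and 4 fell, namely the adaptors Crk and Grb2 at −0.57 ± 0.13 and −0.42 ± 0.10, the HGF-activating protease St14 at −1.78 ± 0.41 and its inhibitor Spint2 (camera adjusted p = 0.245). Without iHRAS* array 5 or 6, 2 rose. Of 14 RAS-ERK output genes, 4 fell, with the feedback inhibitor Spry2 at −1.04 ± 0.16, and Myc rose by 0.65 ± 0.18 (camera adjusted p = 0.111). Myc lost its call without iMet array 1, at 0.58. Without iMet array 1 none rose, and without iHRAS* array 3, 2 rose. The others that fell were Phlda1, Ccnd1 and Ier3, and the number was 1 without iMet array 3 and 2 without iMet array 1 or 5 or iHRAS* array 2. The RAS-ERK list passed without iHRAS* array 4 (adjusted p = 0.034). Of 7 WNT pathway genes, 3 fell, the antagonist Sfrp1 at −2.52 ± 0.39, the stem cell gene Lgr5 at −1.65 ± 0.32 and the receptor Fzd7 at −0.76 ± 0.19, and 2 rose, Apcdd1 by 1.97 ± 0.44 and Wnt5a (camera adjusted p = 0.245). Only 1 rose without any 1 of the iMet arrays or iHRAS* array 1, 4, 5 or 6. The WNT list passed fry (adjusted p = 0.00812), as did the MET list (0.0250). The mean of the 8 WNT genes bright enough over all 16 arrays, Wif1 among them, was 7.5 ± 0.20 (SD, n = 6) in iMet and 8.68 ± 0.21 (SD, n = 6) in iHRAS* tumours, lower in every iMet tumour (exact permutation p = 0.002165; adjusted p = 0.0080). Most of that difference of −1.18 came from Wif1, and for the 7 other genes the means were 8.30 ± 0.19 and 8.61 ± 0.22 (SD, n = 6 each), a difference of −0.32 (exact permutation p = 0.0173, tested after the values were seen). Among 14 interferon response genes, Rsad2 rose by 1.25 ± 0.31 (camera adjusted p = 0.25, and adjusted p = 0.048 without iMet array 1), and 2 rose without iMet array 1 or iHRAS* array 1 or 4. Among 16 hypoxia and glycolysis genes, the phosphofructokinase Pfkp fell by 1.26 ± 0.34 (camera adjusted p = 0.101), and the list passed when any 1 of iMet arrays 2 and 4 or iHRAS* arrays 1, 5 and 6 was left out, at adjusted p = 0.010 to 0.039. Adjusted over the list alone, 2 genes of the MET list rose and 4 fell, 1 RAS-ERK gene rose and 5 fell, 2 WNT genes rose and 3 fell, 1 interferon gene rose and 1 hypoxia gene fell.

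Of 21 oxidative phosphorylation genes, 3 rose (camera adjusted p = 0.547), of which the oxidase subunit Cox6c, at 0.69 ± 0.15, was alone in passing without any 1 of iMet arrays 1 to 5 or iHRAS* arrays 1, 3, 4, 5 and 6; without iMet array 5, 1 fell. Of 14 fibroblast markers, 2 rose and 4 fell, with the growth factor receptor Pdgfra at 0.86 ± 0.16, the matrix gene Fbln1 at −2.69 ± 0.62 and the surface marker Thy1 at −2.16 ± 0.55 (camera adjusted p = 0.564). Only 1 rose without any 1 of iMet arrays 1 to 5 or iHRAS* arrays 1, 3, 5 and 6, and 2 fell without iMet array 1, 3 or 5 or iHRAS* array 1 or 5. None of 7 neutrophil and mast cell markers (camera adjusted p = 0.364) or 9 skeletal muscle markers (adjusted p = 0.528) passed. The fatty acid carrier Fabp4, 1 of 2 adipocyte markers tested, rose by 3.42 ± 0.74 (camera adjusted p = 0.364), and the single red blood cell marker tested, the haem synthesis gene Alas2, rose by 3.33 ± 0.68. No lymphocyte marker was bright enough to be tested. When adjusted over the list alone, 1 oxidative phosphorylation gene rose, 2 fibroblast markers rose and 4 fell, 1 adipocyte and 1 red blood cell marker rose, and no muscle, neutrophil or mast cell marker passed.

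In all, 1687 of 8058 genes passed between the tumour models in limma, 905 higher and 782 lower in iMet tumours. Of these, 608 changed at least 2-fold. The lower bioB and bioC controls coincided with the iHRAS* model, so handling cannot be told apart from it for these genes. Ranges of the groups did not overlap for 864 genes, or 10.7% against 0.216% by chance, of which 837 were among those that passed. Of the 23 lists with at least 2 members tested, 10 passed camera, and 3 held with an estimated correlation, those of p53 targets, of Schwann cell and neural crest markers and of integrins. As deposited, the WNT (adjusted p = 0.0458), RAS-ERK (0.0327), fibroblast (0.0327), protease (0.0415) and hypoxia (0.00467) lists passed too. Hypoxia also passed without iHRAS* arrays 5 and 6 (0.00706), and hypoxia (0.00067) and interferon genes (0.000222) with the covariates. The share of higher calls depended on scaling, with 53.6% here, 56.3% after median centring (820 higher, 636 lower) and 80.1% as deposited (1791 higher, 445 lower), where the median of all genes shifted from 0.03 to 0.23. With the keratinocyte and endothelial means as covariates, 217 genes passed.

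Calls of single genes between the models depended on the setting as well. Of 76 named genes outside the 2 marker lists, 49 were lost with those covariates (adjusted p = 0.0557 to 0.571). Among the largest increases these were Ogn (3.90), Angptl7 (3.62), Hoxb2 (3.82), Tmem100 (2.52), Cavin2 (1.8), Efemp1 (3.87) and Ccl12 (3.59), and among the largest decreases Sox2 (−6.29), Slc14a1 (−6.26), Nefm (−2.92), Fbn2 (−4.69) and Klk6 (−4.71). Egr2 (−1.30), Spry2 (−0.61), Ccnd1 (−0.36), Wasf1 (0.46) and Cox6c (0.38) shrank by over 1.5 times. Itgb3 (−5.09), Vsig4 (2.97) and Rsad2 (1.99) passed at larger values. With the mean of all probe sets of a gene, Spry2 (−0.27, adjusted p = 0.430), Crk (−0.30, 0.338), Grb2 (−0.26, 0.0811), Fscn1 (0.94, 0.138), Cd44 (−0.55) and Pfkp (−0.96) were lost. Sox10 was at −5.0. Grb2 (−0.20, adjusted p = 0.206), Crk (−0.37, 0.0545), Pmel (−1.02) and Plaur (−0.58) were lost as deposited. Lost after median centring were Grb2 (−0.40), Fscn1 (0.43, 0.143), Cox6c (0.47), Pdgfra (0.68) and Phlda1 (−1.08). Ccl12, Vsig4, Mrc1, Dsp and Ccnd1 were lost with no dim filter, and Twist1, Pdgfra and Ccnd1 with melanocytes in the fit. Myc, Ccnd1 and Dsp were lost without iHRAS* arrays 2 and 3, 3 and 4, or 5 and 6. Leaving out arrays 2 and 3 or 3 and 4 also ended the calls of Vsig4, Pfkp and Mrc1, arrays 2 and 3 or 5 and 6 that of Itgb3, arrays 3 and 4 or 5 and 6 that of Perp, arrays 3 and 4 those of Ccl12 and Phlda1, and arrays 5 and 6 those of Tiam1, Fscn1, Rsad2 and Thy1. Ccl12 passed at 1.66 and Phlda1 at −0.62 without arrays 2 and 3.

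In the comparison of iMet tumours with melanocytes, genes of macrophages rose most. Complement C1qa, made by macrophages, rose by 10.30 ± 0.40 log2 (SE), C1qc by 9.36 ± 0.36, C1qb by 8.61 ± 0.56, the cathepsin Ctss by 9.19 ± 0.46, the Fc receptor Fcgr3 by 8.76 ± 0.34 and the lysozyme Lyz1 by 8.61 ± 0.74. The peptidase Mme rose by 8.58 ± 0.58 and the granule proteoglycan Srgn by 8.52 ± 0.43. Largest among the decreases were Igfbp2, which binds insulin-like growth factors, at −8.04 ± 0.98, Foxd3 at −6.99 ± 0.30, Sox2 at −6.88 ± 1.15, the heparan sulphate enzyme Hs6st2 at −5.94 ± 0.72, the brain fatty acid carrier Fabp7 at −5.39 ± 0.87, Ndn at −5.24 ± 0.81, Adam23 at −5.10 ± 0.83 and Nrcam at −5.04 ± 0.61. As above, sizes against levels near background are uncertain. The 3' minus 5' actin signal, a sign of RNA quality, also differed in this comparison, at 0.15 ± 0.07 (SD, n = 6) in iMet tumours and −0.01 ± 0.03 (SD, n = 4) in melanocytes (exact permutation p = 0.00952; adjusted p = 0.022), whereas the same measure of Gapdh did not (exact permutation p = 0.776).

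All 14 macrophage markers rose, also when adjusted over the list alone, with a median of 5.40 (camera adjusted p = 7.7e-18; adjusted p = 0.0992 with an estimated correlation). Endothelial markers rose in 11 of 12, also 11 when adjusted over the list alone, among them Plvap at 7.17 ± 0.32 and Pecam1 at 5.38 ± 0.40 (median 4.29; camera adjusted p = 1.9e-10, adjusted p = 0.0992 with an estimated correlation). Antigen presentation genes rose in 10 of 14, or 12 when adjusted over the list alone, with the class II genes Cd74 and H2-Aa at 5.28 ± 0.72 and 5.73 ± 0.82 (median 2.07; camera adjusted p = 9.34e-07, adjusted p = 0.289 with an estimated correlation). Interferon response genes rose in 9 of 14, or 10 when adjusted over the list alone, with Oasl2 at 5.60 ± 0.86 (median 1.46; camera adjusted p = 6.09e-05, adjusted p = 0.393 with an estimated correlation). Of 14 fibroblast markers, 7 rose, also 7 when adjusted over the list alone, with Pdgfra at 4.65 ± 0.45 and decorin, Dcn, at 4.41 ± 0.48 (median 1.03; camera adjusted p = 0.00313, adjusted p = 0.44 with an estimated correlation). Without melanocyte array 2 or 4, 4 fibroblast markers rose, and the median was 0.66 without array 4. Without both arrays the list mean was 0.55 instead of 1.62 and the list did not pass (adjusted p = 0.264). Of 9 neutrophil and mast cell markers, 6 rose, or 8 when adjusted over the list alone, with S100a8 at 6.81 ± 1.00 and S100a9 at 7.85 ± 1.23 (median 2.65; camera adjusted p = 0.00123, adjusted p = 0.35 with an estimated correlation). Without melanocyte array 2 or iMet array 2 or 5, 3 rose.

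Smaller sets of tissue markers also rose in iMet tumours over melanocytes. Of 10 skeletal muscle markers, 3 rose, with the troponin Tnnc2 at 6.07 ± 1.32 (median 3.02; camera adjusted p = 0.00813, adjusted p = 0.474 with an estimated correlation). The number was 1 without melanocyte array 1 and 6 without iMet array 4. Of 3 adipocyte markers, Fabp4 rose by 8.0 ± 0.88 and the fatty acid receptor Cd36 by 5.37 ± 0.76 (median 5.37; camera adjusted p = 0.0312, adjusted p = 0.289 with an estimated correlation, adjusted p = 0.0657 without melanocyte arrays 2 and 4). Of 2 red blood cell markers, Alas2 rose by 6.22 ± 0.69 (median 3.99; camera adjusted p = 0.038, adjusted p = 0.289 with an estimated correlation), a list result lost without melanocyte array 2 (adjusted p = 0.064), 2 and 4 (0.0835) or 1 and 3 (0.0613) and with no dim filter (0.173), and both rose without melanocyte array 4 or iMet array 3. The lymphocyte marker tested, Cd4, had a difference of 0.45 ± 1.10 that did not pass. Adjusted over the list alone, 3 muscle, 2 adipocyte and 2 red blood cell markers rose, and Cd4 did not pass.

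Neural crest markers fell in iMet tumours, and pigmentation genes went both ways. Of 7 Schwann cell and neural crest markers, 4 fell, also 4 when adjusted over the list alone, with Erbb3 at −4.22 ± 0.40 and Ngfr at −4.84 ± 0.73 beside Foxd3 and Sox2, while Pmp22 rose except without melanocyte array 2 (median −4.22; camera adjusted p = 0.0242, adjusted p = 0.289 with an estimated correlation, adjusted p = 0.0554 after median centring). Of 8 pigmentation genes, Sox10 was at −2.75 ± 0.38, the melanosome transport gene Rab38 at −1.99 ± 0.43, and Pax3 and Pmel also fell, but the receptor Kit rose by 4.41 ± 0.63 and the lineage regulator Mitf by 1.89 ± 0.31 (camera adjusted p = 0.542). Of 14 keratinocyte markers, 8 fell, also 8 when adjusted over the list alone, with the basal keratin Krt5 at −4.03 ± 1.11 and the desmosome gene Pkp1 at −3.36 ± 1.00, and 3 rose, with Epcam at 3.35 ± 0.80 (median −2.79; camera adjusted p = 0.431). The number that fell was 3 without melanocyte array 2 or 4, 4 without melanocyte array 1 or iMet array 1 or 5, and 5 without iMet array 4; the number that rose was 1 without melanocyte array 1 or 3 and 2 without melanocyte array 4. In melanocytes Krt5 and Krt14 stood at the 98.8th and 99.0th percentile of signal. Of 11 p53 targets, 7 fell, or 10 when adjusted over the list alone, with Pmaip1 at −3.28 ± 0.35, Phlda3 at −1.60 ± 0.20 and Mdm2 at −1.46 ± 0.36 (median −1.01; camera adjusted p = 0.000349, adjusted p = 0.0992 with an estimated correlation).

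Cell division genes gave a weak result against melanocytes. Of 22, 4 rose, with the proliferation marker Mki67 at 1.32 ± 0.22 and Ccnb2 at 1.58 ± 0.28, and 1 fell, and when adjusted over the list alone 2 rose (median 0.40; camera adjusted p = 0.038, adjusted p = 0.632 with an estimated correlation). The list missed the threshold without melanocyte array 1, 3 or 4 or iMet array 1, 3 or 4, with adjusted p = 0.055 to 0.397, and also with the deposited scaling (adjusted p = 0.088) or median centring (adjusted p = 0.072) and in fry (adjusted p = 0.194). Its median was 0.80 without melanocyte array 2 and 0.098 without melanocyte array 3, and its mean turned to −0.066 without melanocyte arrays 1 and 3. Its number of increases was 13 without melanocyte array 2 and 2 without any 1 of the other melanocyte arrays or iMet arrays 1 to 5, and none fell without melanocyte array 1 or 2 or iMet array 2, 5 or 6. Melanocyte array 2 had the highest cell division mean of its group, 10.4 against a group mean of 9.33 ± 0.76 (SD, n = 4). RAS-ERK output genes rose in 6 of 14, with Spred1 at 1.10 ± 0.16, the AP-1 factor Fosl1 at 2.63 ± 0.43 and the phosphatase Dusp6 at 1.57 ± 0.29, and when adjusted over the list alone 6 rose and 1 fell (median 0.41; camera adjusted p = 0.0312, adjusted p = 0.44 with an estimated correlation). The list missed the threshold without melanocyte array 4 (adjusted p = 0.083) and as deposited (0.0545), and without melanocyte arrays 2 and 4 its mean was 0.20 instead of 0.64 (adjusted p = 0.235). Its median was 0.67 without melanocyte array 1 and 0.26 without iMet array 6, and 1 member fell without iMet array 2 or 4.

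Other lists did not pass as sets in this comparison. Of 15 genes around the MET receptor, 2 rose, Met and Hgf, and 5 fell, with Gab1 at −1.45 ± 0.29 (camera adjusted p = 0.519); without any 1 of melanocyte arrays 1 and 3 or iMet arrays 1 and 3 to 6, 1 rose. Of 13 mesenchymal transition genes, 4 rose and 2 fell, with Twist1 at 2.90 ± 0.53, Snai1 at 2.02 ± 0.34 and Cdh2 at −2.22 ± 0.28 (camera adjusted p = 0.466). Of 17 proteases and inhibitors, 4 rose, with the gelatinase Mmp9 at 3.48 ± 0.61 and Ctsb at 1.70 ± 0.19 (camera adjusted p = 0.0535); the list passed without melanocyte array 1 or 3 or iMet array 1, 5 or 6, at adjusted p = 0.018 to 0.047, without melanocyte arrays 1 and 3 (0.00119) and with no dim filter (0.0324), and 1 member fell without melanocyte array 2 or iMet array 2. Of 16 adhesion receptors, 4 rose, with Vcam1 at 3.70 ± 0.88, and 5 fell, with L1cam at −3.46 ± 0.35 (camera adjusted p = 0.469); 2 rose without melanocyte array 2. Of 19 actin and motility genes, 6 rose, with the haematopoietic genes Dock2 at 4.48 ± 0.63 and Rac2 at 3.69 ± 0.61, and 3 fell, with Fscn1 at −0.90 ± 0.16 (camera adjusted p = 0.466). Of the 4 invasion candidates, which are not independent evidence, Acp5 rose by 5.0 ± 0.67 and Vsig4 by 2.96 ± 0.55 while Fscn1 fell (camera adjusted p = 0.286). Of 8 WNT genes, Fzd7 fell by 1.48 ± 0.20 (camera adjusted p = 0.608), and 2 fell without melanocyte array 1 or iMet array 6. Of 16 hypoxia genes, Egln3 rose by 3.39 ± 0.76 and P4ha2 fell by 2.23 ± 0.44 (median −0.16, mean 0.04; camera adjusted p = 0.637); 2 fell without melanocyte array 3 or iMet array 4, and 2 rose without melanocyte array 3 or iMet array 6. Of 21 oxidative phosphorylation genes, 7 fell, with Ndufv1 at −0.53 ± 0.12, and 1 rose (camera adjusted p = 0.23); the number that fell was 4 to 9 without single arrays, lowest without melanocyte array 2 and highest without iMet array 5, and none rose without any 1 of the melanocyte arrays or iMet arrays 1 to 5. That list passed after median centring (adjusted p = 0.0360). When adjusted over the list alone, 2 genes rose and 5 fell in the MET list, 4 and 3 in the mesenchymal list, 4 and 0 among proteases, 4 and 6 among adhesion receptors, 7 and 4 among actin genes, 2 and 1 among the invasion candidates, 0 and 1 in the WNT list, 1 and 1 in the hypoxia list and 1 and 8 in oxidative phosphorylation.

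Altogether 3040 of 8651 genes passed between iMet tumours and melanocytes, 1418 higher and 1622 lower, with 1381 changed at least 2-fold. Other cells in the tumour samples cannot be told apart here from changes in the melanoma cells. Ranges did not overlap for 27.7% of genes against 0.952% by chance, and 2165 of the genes that passed were among these. Of 24 lists, 13 passed camera and none held with an estimated correlation, while 16 passed fry, among them proteases and integrins (adjusted p = 0.0350 each), the invasion candidates (0.00055) and the WNT list (0.00241), which camera did not call. The share of higher calls was 46.6%, against 55.5% with the deposited scaling (1508 higher, 1209 lower) and 33.6% after median centring (1173 higher, 2319 lower), which moved the median of all genes to −0.22. Without melanocyte arrays 2 and 4, 16 of 94 named genes were lost, among them Mdm2 (−0.49, adjusted p = 0.114), Rab38 (−1.09, 0.0621), Krt5 (−2.91, 0.153), Pkp1 (−2.77, 0.147) and Vcam1 (3.04, 0.0712), and Twist1 (1.47), Snai1 (1.31) and Dusp6 (0.99) passed at smaller values. Mdm2 was at −2.43 without melanocyte arrays 1 and 3 and at −0.90 with array weights. With the mean of all probe sets Ndn was at −3.47, Sox10 at −4.72, Fscn1 at −1.40 and Fabp4 at 4.82.

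The comparison of iHRAS* tumours with melanocytes was read in the same way. C1qa rose by 9.67 ± 0.40 log2 (SE), Ctss by 8.95 ± 0.46, Srgn by 8.85 ± 0.43, C1qc by 8.66 ± 0.36, the endothelial and myeloid receptor gene Cd93 by 8.65 ± 0.37 and Fcgr3 by 8.37 ± 0.34. The neurofilament gene Nefl rose by 8.28 ± 0.78 and the secreted peroxidase Gpx3 by 8.23 ± 0.35. Among the largest decreases were C1qtnf3 at −5.21 ± 0.94, Igfbp2 at −5.17 ± 0.98, the potassium channel Kcna1 at −4.66 ± 0.63, the myelin regulator Myrf at −4.53 ± 0.20, the homeobox genes Hoxb9 and Hoxb2 at −4.51 ± 1.03 and −4.26 ± 0.78, Depdc7 at −4.39 ± 0.68 and Cdk18 at −4.30 ± 0.79. The bioB control was lower on these tumour arrays than on the melanocyte arrays, at −0.99 (exact permutation p = 0.00476; adjusted p = 0.0196).

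All 14 macrophage markers and all 14 antigen presentation genes rose in iHRAS* tumours over melanocytes, also when adjusted over the list alone. Macrophage markers had a median of 5.09 (camera adjusted p = 5.32e-15; adjusted p = 0.216 with an estimated correlation) and antigen presentation genes of 3.08 (camera adjusted p = 8.76e-09; adjusted p = 0.351 with an estimated correlation), with H2-K1 at 2.97 ± 0.28 and Cd74 at 6.63 ± 0.72. Of 12 endothelial markers, 11 rose, also 11 when adjusted over the list alone, with Vwf at 6.06 ± 0.73 and Plvap at 5.93 ± 0.32 (median 2.86; camera adjusted p = 8.06e-08, adjusted p = 0.341 with an estimated correlation). Of 14 fibroblast markers, 8 rose, also 8 when adjusted over the list alone, with Lum at 4.73 ± 0.84 and Dcn at 3.98 ± 0.48 (median 1.69; camera adjusted p = 0.00033, adjusted p = 0.563 with an estimated correlation). The fibroblast median was 0.97 without melanocyte array 4, and without melanocyte arrays 2 and 4 the mean was 0.88 instead of 1.95 (adjusted p = 0.0790). Of 9 neutrophil and mast cell markers, 6 rose, or 8 when adjusted over the list alone, with S100a9 at 7.56 ± 1.23 and the mast cell tryptase Tpsb2 at 5.01 ± 0.78 (median 3.78; camera adjusted p = 0.000549, adjusted p = 0.459 with an estimated correlation). Of 14 interferon response genes, 10 rose, also 10 when adjusted over the list alone, with Oasl2 at 5.38 ± 0.86 and Irf1 at 1.39 ± 0.37 (median 1.28; camera adjusted p = 0.00226, adjusted p = 0.605 with an estimated correlation). That number was 6 without melanocyte array 2 or iHRAS* array 4 and 5 without melanocyte array 4.

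Cell division genes gave a weak result in iHRAS* tumours as well. Of 22, 6 fell and none rose, also 6 when adjusted over the list alone, with Pcna at −0.86 ± 0.20 and Mcm4 at −0.77 ± 0.21, and Ccna2 fell by 1.11 ± 0.32, and was at −0.66 without melanocyte array 2 (median −0.67; camera adjusted p = 0.0164, adjusted p = 0.605 with an estimated correlation). The list missed the threshold without melanocyte array 2 (adjusted p = 0.294, median −0.30), without melanocyte arrays 2 and 4 (0.660, with a mean of −0.16 instead of −0.62) and in fry (0.0762), and 11 members fell without melanocyte array 3. RAS-ERK output genes rose in 7 of 14 and fell in 1, Myc, or 9 and 1 when adjusted over the list alone. Dusp6 rose by 1.94 ± 0.29, Fosl1 by 2.05 ± 0.43, the cyclin Ccnd1 by 1.68 ± 0.23 and Spred1 by 1.44 ± 0.16 (median 0.96; camera adjusted p = 0.00238, adjusted p = 0.459 with an estimated correlation). Without melanocyte array 1 or 2 no member of the RAS-ERK list fell. Of 17 matrix proteases and inhibitors, 7 rose and 1 fell, or 7 and 2 when adjusted over the list alone, with Timp1 at 2.05 ± 0.24, Ctsb at 1.81 ± 0.19 and Timp2 at −0.99 ± 0.19 (median 0.64; camera adjusted p = 0.0205, adjusted p = 0.605 with an estimated correlation). The protease list missed the threshold without melanocyte array 2 (adjusted p = 0.068), 4 (0.062) or both (0.324) or iHRAS* arrays 5 and 6 (0.0713), its median was 0.98 without melanocyte array 3, 4 rose without melanocyte array 4, and 2 members fell without melanocyte array 2 or iHRAS* array 6.

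Epithelial genes of the iHRAS* tumours stood above melanocytes in part. Of 14 keratinocyte markers, 5 rose, with Epcam at 7.01 ± 0.80, Cdh1 at 5.05 ± 0.66, Krt1 at 7.56 ± 1.54 and the cornified envelope gene Lor at 3.43 ± 0.94 (camera adjusted p = 0.168); the list median was −0.11 where its mean was 1.5 and camera pointed up. Of 7 Schwann cell and neural crest markers, Egr2 rose by 3.01 ± 0.64 and Pmp22 by 1.59 ± 0.30, and Ngfr was at −2.08 ± 0.73 (camera adjusted p = 0.465). Ngfr lost its call without melanocyte array 1 or 3 or iHRAS* array 1, 2 or 3, at −1.94 to −1.73, and 2 members fell without melanocyte array 4. Of 8 pigmentation genes, Kit rose by 4.45 ± 0.63 and Mitf by 1.67 ± 0.31 while Rab38 fell by 1.57 ± 0.43 (camera adjusted p = 0.419), and 2 fell without iHRAS* array 3. Of 11 p53 targets, Zmat3 fell by 0.79 ± 0.20 and Bbc3 was at −0.54 ± 0.16 (camera adjusted p = 0.465). Without melanocyte array 3, Bbc3 missed the threshold at −0.41, and 3 members rose and 1 fell. Adjusted over the list alone, 5 keratinocyte markers rose, 2 neural crest markers rose and 1 fell, 2 pigmentation genes rose and 1 fell, and 2 p53 targets fell.

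Remaining lists did not pass as sets for iHRAS* tumours. Of 15 genes around the MET receptor, 3 rose and 5 fell, with St14 at 2.35 ± 0.52 and Gab1 at −1.19 ± 0.29 (median −0.04, mean 0.01; camera adjusted p = 0.904), and 1 rose and 3 fell without melanocyte array 2 or 4. Of 13 mesenchymal transition genes, 4 rose and 1 fell, with Tgfbi at 2.16 ± 0.41, Zeb1 at 1.23 ± 0.23 and Snai2 at −1.96 ± 0.40 (camera adjusted p = 0.366), and 2 fell without melanocyte array 2 or iHRAS* array 1. Of 16 adhesion receptors, 4 rose, with Icam1 at 3.22 ± 0.57 and Alcam at 2.86 ± 0.69 (camera adjusted p = 0.354), and 1 fell without melanocyte array 3 or 4 or iHRAS* array 1. Of 19 actin genes, 5 rose and 2 fell, with Dock2 at 3.96 ± 0.63 and Fscn1 at −1.43 ± 0.16 (camera adjusted p = 0.478); 3 rose without melanocyte array 2 or iHRAS* array 3 or 4, and 1 fell without melanocyte array 2 and 3 without iHRAS* array 3. Of the 4 invasion candidates, Acp5 rose by 3.74 ± 0.67 and Fscn1 and Ndc80 fell, Ndc80 to −1.45 ± 0.30 (median −0.11, mean 0.52; camera adjusted p = 0.702). Of 8 WNT genes, the inhibitor Wif1 rose by 7.78 ± 1.23 and Sfrp1 by 1.80 ± 0.41, and Fzd7 and Apcdd1 fell (camera adjusted p = 0.458); 1 fell without melanocyte array 1 or iHRAS* array 2, and 4 rose without iHRAS* array 4. Of 16 hypoxia genes, Egln3 rose by 4.22 ± 0.76 and Pfkp by 1.17 ± 0.34 and P4ha2 fell (camera adjusted p = 0.465). None of them fell without melanocyte array 1, 2 or 3 or iHRAS* array 4, 5 or 6, and 2 fell without iHRAS* array 3, whereas 3 rose without iHRAS* array 5. Of 21 oxidative phosphorylation genes, 6 fell, with Sdhc at −0.53 ± 0.10 (camera adjusted p = 0.0798). Of 10 muscle markers, 2 rose, with Tnnc2 at 4.59 ± 1.32 (camera adjusted p = 0.0633); the list passed without iHRAS* array 1 (adjusted p = 0.022) or 6 (adjusted p = 0.016), and 1 rose without melanocyte array 1 or 4 or iHRAS* array 2, 3 or 5. Fabp4 and Cd36 rose by 4.59 ± 0.88 and 3.84 ± 0.76 among 3 adipocyte markers (camera adjusted p = 0.112) and Alas2 by 2.89 ± 0.69 among 2 red blood cell markers (camera adjusted p = 0.465). The lymphocyte marker Cd4, at 2.75 ± 1.10, did not pass except without iHRAS* array 2 (3.44) or 3 (3.36). When adjusted over the list alone, 3 genes rose and 6 fell in the MET list, 4 and 1 in the mesenchymal list, 3 and 0 among adhesion receptors, 5 and 2 among actin genes, 2 and 2 among the invasion candidates, 3 and 2 in the WNT list and 2 and 0 in the hypoxia list, 4 oxidative phosphorylation genes fell, and 1 muscle, 2 adipocyte, 1 red blood cell and 1 lymphocyte marker rose.

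In total 3404 of 8651 genes passed between iHRAS* tumours and melanocytes, 1565 higher and 1839 lower, with 1489 changed at least 2-fold. Ranges did not overlap for 25.3% of genes against 0.952% by chance, and 2091 of those that passed were among these. Of 24 lists, 9 passed camera and none held with an estimated correlation, and 13 passed fry, among them pigmentation (adjusted p = 0.0386), the invasion candidates and the WNT list (0.00347 each), oxidative phosphorylation (0.0129) and adipocyte markers (0.0102), which camera did not call. Of the lists that did not pass camera here, keratinocyte genes did so without melanocyte arrays 2 and 4 (adjusted p = 0.0225), mesenchymal genes without melanocyte arrays 1 and 3 (0.0386), oxidative phosphorylation as deposited (0.0254) and after median centring (0.0497), and muscle as deposited (0.0106), after median centring (0.0115), with no dim filter (0.0484) and without iHRAS* arrays 5 and 6 (0.0331). The share of higher calls was 46.0%, against 35.1% with the deposited scaling (1321 higher, 2438 lower; median of all genes −0.22) and 34% after median centring (1326 higher, 2575 lower; median −0.23), where the median here was −0.09. Without melanocyte arrays 2 and 4, 21 of 96 named genes were lost, among them Mcm4 (−0.32, adjusted p = 0.228), Ccna2 (−0.63), Rab38 (−0.67, 0.239), Fosl1 (1.30), St14 (1.5), Gab1 (−0.97), Alcam (1.70), Egr2 (1.76), Lor (3.03), Tnnc2 (4.63), Pfkp (1.14), Fzd7 and Apcdd1, while Pcna (−0.57), Pmp22 (0.90), Tgfbi (3.29) and Zmat3 (−1.25) passed. Without melanocyte arrays 1 and 3, 11 were lost, among them Zmat3 (−0.32), Bbc3 (−0.33), Irf1 (1.32), Ngfr (−1.11), P4ha2 (−0.92), Tnnc2, Pfkp and Apcdd1, and Tgfbi was at 1.03, Rab38 at −2.48 and Mcm4 at −1.23. With the mean of all probe sets Zeb1 (0.54, adjusted p = 0.253), Pfkp (0.70) and Sfrp1 (1.16) were lost, and Cd93 was at 4.37, Tpsb2 at 2.55, Fabp4 at 1.71 and Fscn1 at −2.35. Mcm4 (−0.49, adjusted p = 0.0502) and Pfkp (0.88) were lost with array weights, Bbc3 (−0.44) as deposited, and Ngfr (−1.28), Tnnc2 (3.62), Apcdd1 (−0.85) and Pfkp without iHRAS* arrays 2 and 3.

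**Figure D4:**
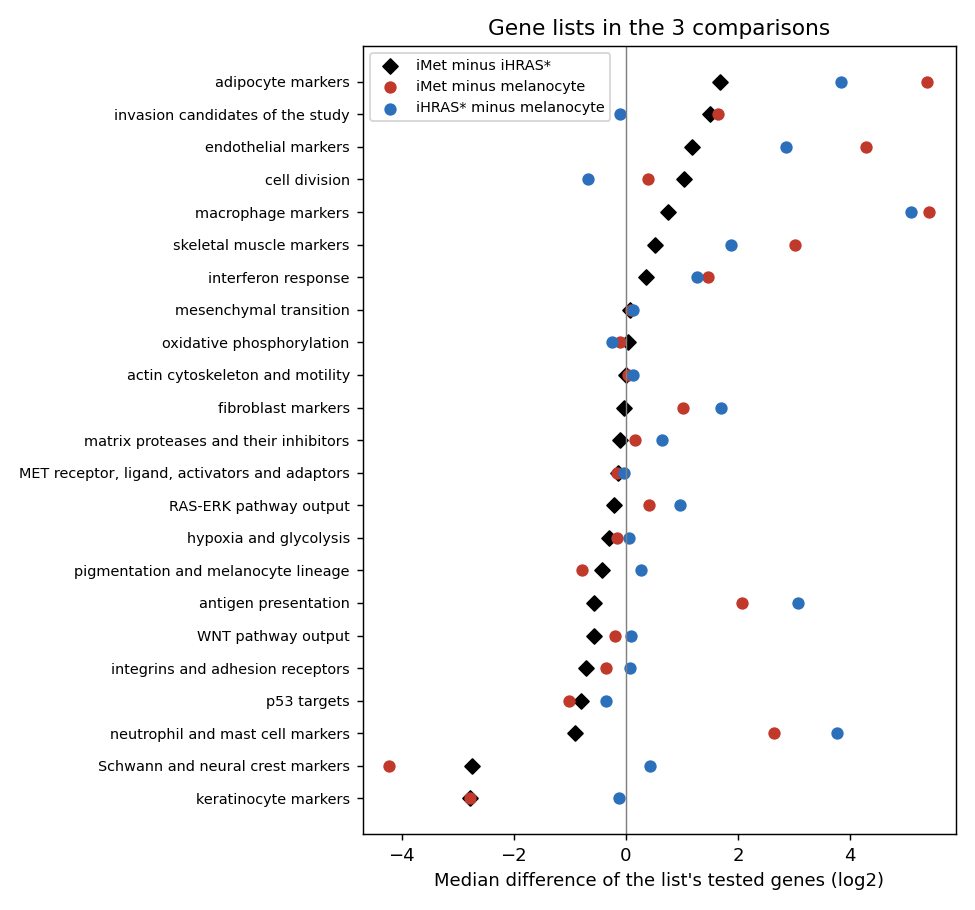
Median log2 difference of each of 23 gene lists (y axis) for iMet minus iHRAS* tumours (black diamonds), iMet tumours minus melanocytes (red) and iHRAS* tumours minus melanocytes (blue). Macrophage markers lie at 5.40 and 5.09 against melanocytes.

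Against melanocytes, the tumour models shared 1980 genes called in the same direction, 992 higher and 988 lower, and 28 called in opposite directions. Nrcam fell by 5.04 ± 0.61 in iMet tumours and rose by 2.43 in iHRAS* tumours, Aldh1a3 was at −2.98 and 2.59, the natriuretic peptide gene Nppb at −1.56 and 2.84, and Ggct at −1.65 and 2.63. Gdnf, a neurotrophic factor, and its receptor gene Gfra1 were at −1.43 and −1.81 in iMet tumours and at 1.11 and 1.67 in iHRAS* tumours. Met (1.18 and −1.35), the neuronal growth cone gene Dpysl3 (0.82 and −0.99) and the kinase gene Prkca (0.61 and −0.73) took the other direction. These genes were taken from the 28 after their values were seen. Of the 1687 genes that passed between the models, 425 also passed in the same direction in iMet tumours alone against melanocytes. In iHRAS* tumours alone 579 passed in the opposite direction, and 390 passed in neither. As bioB and bioC were lower on iHRAS* arrays alone, handling cannot be told apart from the model for the 579 or the 28.

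Both comparisons use the same 4 melanocyte arrays, which by itself makes their differences resemble each other. The correlation of the 2 sets of differences across genes, which are not independent replicates, was 0.809, against 0.600 on average for simulated unchanged groups (0.547 to 0.643 in 100 runs), and the covariance was 1.27 against 0.0871. The same sign was found for 77.4% of genes against 70.4% in the simulation. No simulated run gave a shared call, which unchanged groups make nearly certain. Independent lists of the same lengths would share 257 higher and 345 lower genes. With the melanocyte arrays divided so that each model had 2 of its own, 944 to 1096 genes were shared and 1 to 132 were opposite.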

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

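The tests of array scaling, hybridisation, cell mixture, melanoma cell share, Schwann cells, keratinocyte RNA and array exchange were chosen only after the result was seen, as were the conditions of 2 standard errors for the cell share and of more than 2 myelin transcripts for Schwann cells. The search for outlying arrays and the splits were fixed beforehand. The hybridisation test took the place of one fixed beforehand on quantile-normalized values, which was void because that normalization largely sets its outcome.

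Arrays far from the rest of their group were sought in 216 groups of values, of which chance gives about 10.8 and 11 were found. The 3' minus 5' actin signal was 1.12 in iHRAS* tumour 4 against 0.06 to 0.30 in the others. Among list means, pigmentation genes averaged 6.98 in melanocyte 4 (others 6.46 to 6.48), the MET list 8.51 in melanocyte 1 (others 8.57 to 8.58), integrins 9.32 in iMet tumour 4 (others 8.91 to 8.97) and the WNT list 8.28 in iHRAS* tumour 3 (others 8.68 to 8.88). Among genes, Efemp1 was at 10.17 in iMet tumour 4 (others 11.37 to 11.92), Fabp7 at 1.16 in iHRAS* tumour 3 (others 3.57 to 4.82), Gpx3 at 3.13 in melanocyte 4 (others 2.27 to 2.35) and Igfbp2 at 2.84 in iMet tumour 1 (others 5.07 to 6.21). Met was at 8.39 in iMet tumour 2 (others 9.49 to 9.98) and at 5.42 in iHRAS* tumour 1 (others 6.99 to 7.46).

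The models differed in direction against melanocytes for 3 results. Met differed between the models by 2.53, with 1.18 and −1.35 against melanocytes. Genes called in opposite directions numbered 28, and all 28 passed between the models, which this selection nearly ensures. The cell division list differed by 1.03, with medians of 0.40 in iMet and −0.67 in iHRAS* tumours, and neither call against melanocytes was secure. With an estimated correlation the adjusted p was 0.632 and 0.605, and in fry 0.194 and 0.0762. The former was lost without melanocyte array 1, 3 or 4 or iMet array 1, 3 or 4, as deposited and after median centring. The latter was lost without melanocyte array 2 or 2 and 4. Without single arrays the medians ran from 0.098 to 0.80 and from −0.88 to −0.30, and without melanocyte arrays 1 and 3 the mean in iMet tumours was −0.066.

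The higher cell division genes of iMet tumours were weighed against technical causes. Centring each array on its median lowered the list median only from 1.26 as deposited to 1.05, which argues against a shift of whole arrays as the whole cause; in the deposited values, whose distributions were not made equal, 10000 random lists matched on signal level had a typical median of 0.25 and at most 0.63, which argues against a weaker hybridisation of the iHRAS* arrays that depends on level. With keratinocyte and endothelial marker means as covariates the list median was 0.92 and its mean went from 1.01 ± 0.15 (SE) to 0.93 ± 0.19 (SE), so the mixture those markers measure was not the whole cause, although 4 of 22 genes then passed instead of 19, as the median standard error grew from 0.19 to 0.28. Other cells that these markers do not measure, and any handling step shared by a model's arrays, stay open. A difference between the models in the tumour cells themselves was not tested and stays open too.

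The lower neural crest genes of iMet tumours were weighed in the same way. A lower share of melanoma cells, with the mix of other cells unchanged, would raise all other markers alike. Endothelial less keratinocyte markers differed by 3.45 ± 0.96 (SE, n = 12 tumours), as the former were higher and the latter lower. This argues only against that simple case. A lower share together with a changed mix of other cells would also shift markers unequally, so the test cannot decide about it. Schwann cells in the iHRAS* tumours cannot be told apart. Only Mbp and Pmp22 were analysed here among myelin transcripts (median −0.45), too few to decide. The melanocyte arrays also gave signal for Foxd3, Sox2 and Erbb3, at 8.77, 7.47 and 10.08, and none of these genes is on another list. Which cells of the melanocyte samples gave that signal was not tested, so it does not decide about Schwann cells. A difference between the models in the tumour cells themselves was not tested and stays open.

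Keratinocyte genes were bright in the melanocyte arrays. Of 9 basal layer markers measured, 8 lay above the 75th percentile there, with Krt5 and Krt14 at 98.8 and 99.0 and Krt15 at 45.9, which is consistent with keratinocyte RNA in those samples; the cells' own expression was not excluded. Exchange with a tumour array is argued against by macrophage markers, whose lowest tumour mean lay 3.89 above the highest melanocyte mean. None of these keratinocyte markers is on another list. No biological explanation was tested.

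Random splits of the arrays, 100 per result with the real one among them, show where chance can be excluded. It can for the genes called, since only 1 split of each comparison, the real one, reached its count: 1687 against at most 7 in other splits between the models, 3040 against 46 for iMet tumours and 3404 against 657 for iHRAS* tumours. The splits with 46 and 657 kept all 4 melanocyte arrays together, with iMet tumours 4 and 6 or iHRAS* tumours 3 and 4, and so hold part of the real contrast. For the 1980 shared genes (highest other 3) the splits cannot decide, as random groups leave few calls to share. For the number of lists that passed camera, 2 splits reached the 13 of iMet tumours against melanocytes (highest other 13). Between the models 8 splits reached the real 10 (highest other 11), and for iHRAS* tumours against melanocytes 19 reached the real 9 (highest other 12), so for these numbers of lists chance cannot be excluded. Other splits passed a median of 6 lists between the models and of 7 (iMet) and 6 (iHRAS*) against melanocytes. So a camera pass at the preset correlation is weak evidence for any 1 list.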

How the results depend on the processing

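Settings without pairs of arrays or with covariates were chosen only after the data were seen, and the others were planned. Counts of called genes stayed within 1.5 times of 1687, 3040 and 3404 under the other scalings, filters, probe set choices, variance models and arrays in the fit, and when single arrays were left out (1273 to 1774, 2429 to 2853 and 2712 to 3569). Stricter thresholds lowered them by construction, to 769, 1754 and 2073 at an adjusted p under 0.01 and to 608, 1381 and 1489 at a change of at least 2-fold. With keratinocyte and endothelial covariates 217 genes passed between the models, 209 of them among the 1687; 2 more coefficients and wider errors contribute to this by construction. Without melanocyte arrays 2 and 4, 2169 genes passed for iHRAS* tumours. That setting has fewer arrays and other keratinocyte and fibroblast means, and no cause was tested.

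With an estimated correlation 3, 0 and 0 lists passed camera in the 3 comparisons. The shared genes numbered 1079 at an adjusted p under 0.01, 1268 without melanocyte arrays 2 and 4, and 994, 1040, 960, 944, 1096 and 1023 when the melanocyte arrays were divided between the models, where each fit has fewer arrays. They were 1846 as deposited and 2515 after median centring, and 1498 to 1883 when single melanocyte arrays were left out.

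Met in iMet tumours against melanocytes kept its direction but missed the threshold after median centring (1.02), with no dim filter (1.18), with all probe sets (1.18), with the replicate block (1.05) and without melanocyte arrays 1 and 3 (0.45); leaving out single arrays gave 0.84 to 1.46. The adjusted p over all alternatives ran from 0.00982 to 0.522. In iHRAS* tumours Met missed it with array weights (−1.03), with only the compared groups in the fit (−1.35) and without melanocyte arrays 2 and 4 (−0.61), and leaving out single arrays gave −1.69 to −1.04, with an adjusted p of 0.0056 to 0.388 over all alternatives. More genes tested explains the loss with no dim filter or all probe sets, and the cause was not tested for the others. Values turned over in 2 cases. Cttn between the models was 0.060 with all its probe sets averaged, and the cell division mean in iMet tumours was −0.066 without melanocyte arrays 1 and 3; the cause was not tested.

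Of 2218 values for genes named between the models, 2026 kept direction and side of the threshold, 191 lost significance and 1 turned over. Against melanocytes 2057 of 2124 (iMet) and 2357 of 2453 (iHRAS*) were kept and the rest lost significance. Of the values of lists, 461 of 504, 385 of 432 and 471 of 504 were kept, 25, 33 and 17 lost and 18, 13 and 16 gained significance, and 1 turned over.

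Expression did not pair the samples by replicate number. Deviations of arrays with the same number correlated at −0.22 to 0.11 between the models, over 0.1 in 2 of 6 pairs, and at −0.07 to 0.10 against melanocytes, with 1 array per comparison closest to its own number. With that number as a block, 1186, 2401 and 2832 genes passed. Over arrays 1 to 4, bioD rose in melanocytes (11.99 to 12.31) and iMet tumours (11.93 to 12.33) and fell in iHRAS* tumours (12.37 to 12.15). Shared handling by number stays open. Genes under the 40th percentile were not tested, and large differences against such levels have an uncertain size.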

Other observations

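All values in this part were picked out only after they were seen, with no test planned or explanation offered. One iMet tumour, number 5, had the highest signal of all 16 arrays for several immune and fat cell transcripts. The B cell genes Ms4a1, Cd79a and Cd79b were at log2 10.24, 9.07 and 8.88 there, against at most 6.11, 5.65 and 6.93 elsewhere. The adipocyte hormone gene Adipoq was at 10.31 (at most 7.27 elsewhere), and the neutrophil granule genes Mpo, Camp and Ltf at 8.44, 9.08 and 10.16 (at most 5.19, 5.24 and 8.47). The T cell gene Cd3d was at 8.28, 7.10, 7.89 and 5.59 in iHRAS* tumours 1, 4, 5 and 6, at 3.11 and 1.35 in iHRAS* tumours 2 and 3, and averaged 2.98 in iMet tumours and 2.33 in melanocytes. Of these genes Ltf alone was bright enough on enough arrays to be tested, against melanocytes, and its differences of 1.57 in iMet and 0.53 in iHRAS* tumours did not pass.

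Keratins of different layers had different levels. Krt1, a keratin of the upper epidermis, averaged 3.44 in melanocytes and 8.21 in iMet tumours and lay at 7.94 to 13.05 in iHRAS* tumours, and it rose over melanocytes in both models. The basal keratin Krt5 averaged 12.57 in melanocytes, 8.54 in iMet tumours and 11.07 in iHRAS* tumours, and fell in iMet tumours alone. Neither passed between the models. Among iMet tumours Krt1 ranged from 4.33 to 12.45, and among melanocyte arrays Krt5 ranged from 11.05 to 13.69.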
